A study of Homo sapiens with 6 samples.

How the data were processed

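The deposited table held 1 column of whole numbers per library for 18679 genes, and its unit was recorded as score, since the authors had multiplied gene read counts by a factor per library and rounded the results. From the values this was median-of-ratios scaling, because the median ratio of each column to the geometric mean of the 6 was between 1.0040 and 1.0046. Such scaling leaves some whole numbers absent where the factor exceeds 1 and makes some more frequent where it is below 1. The pattern among the low values gave factors between 0.8092 and 1.1538, by which the deposited values were divided to estimate assigned reads. Per the submitters' processing notes the tools were FastQC, Trimmomatic 0.33, STAR 2.5.3a, featureCounts 1.4.5-p1 of Subread and DESeq2 (version given as 1.62) with the hg38 (GRCh38) genome. Their parameters, the strand setting of the counting and any filter on low genes were not stated, and the lowest mean of a gene over the 6 libraries was 5.67. Per the labels' protocols VPA was dissolved in water, medium with VPA was renewed each day, water served as control, and libraries were made from total RNA with a stranded kit after DNase treatment. Gene identifiers are Ensembl identifiers per the file headers, and coordinates are those of the table on GRCh38, which match GENCODE 29 for 18678 genes.

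Genes were kept with a value of at least 10 in at least 2 libraries, which left out 10. The log2 of value + 1 was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with the 3 groups and all 6 libraries in 1 fit and 3 residual degrees of freedom. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The fit, the filter, the naming rule, 44 gene lists and the alternatives were fixed before the data were examined, except 2 alternatives and the tests named as later choices in the closing section. Lists were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 41 lists with at least 5 measured members, and also with an estimated correlation and with fry. The estimated correlation rests on only 3 residual degrees of freedom, and camera with it called 0 lists in each comparison. A call lost there therefore does not by itself show that a list was unchanged. The fry test asks whether the genes of a list move on balance in 1 direction, and does not compare them with other genes. Counts adjusted over the list alone use the same test with the p-values of the list's members only. Listed genes absent from the table were not measured. A gene near 0 in the control passes the filter only through libraries where it is higher. Lists with many absent members therefore lean toward rises. TWIST1, which the rule also named, was not analysed here.

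Genes were named by a rule. Part of it took, in each comparison, the 8 called protein-coding genes with the largest rise and the 8 with the largest fall among those with a mean of at least 100 in the higher group and no overlap between the libraries of the groups. Another part took up to 3 risen and 3 fallen called members of each list with a mean of at least 20 in the higher group. A last part named CDH1, EPCAM, VIM, CDH2, FN1, ZEB1, SNAI1, SNAI2, CDKN1A, H1F0, MYC, MKI67, HDAC1, HDAC2, HDAC3, HDAC8, KRT19 and TGFB1 whatever their result. Some genes that the rule chose are not reported here.

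Where both libraries of a group were at 0, the fold was computed against a floor of 3 reads over that group. With an estimated 1 to 3 reads a ratio is given with an exact conditional 95% interval. The overlap of the doses was set beside 100 simulations in which the 3 groups were drawn with the same mean for each gene and the spread of the fit. In a self-test on simulated data with 200 changed genes, 10 runs recovered 5.22%, 53.0% and 85.2% of 1.5-fold, 2-fold and 4-fold changes in the 1 mM setting and 5.52%, 51.2% and 85.5% in the 6 mM setting, with 8.59% and 8.62% of calls false. In the same runs 10 of 10 lists of 25 genes shifted 1.5-fold were found and 0 of 200 unchanged lists were called. Genes were drawn independently of each other in these runs, so false calls of lists of correlated genes were not tested. Far fewer genes were changed there than were called in the data, and each gene had the same spread in all groups. The rates of recovery and of false calls need therefore not hold for the data. The library factors were recovered from simulated counts within 0.0072%. Further calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Exon overlaps of the named genes were taken from GENCODE 29, and a share of exonic bases above 20% is stated beside a gene as uncertain assignment of its reads.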

Results

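RNA was measured in Panc-1 cells, an established human line from a pancreatic ductal carcinoma, that had been kept for 5 days with or without valproic acid (VPA). VPA is a branched short-chain fatty acid that inhibits class I histone deacetylases, the enzymes that remove acetyl groups from histones. The 3 groups were control cells, cells with 1 mM VPA and cells with 6 mM VPA, with 2 libraries in each. By its title the study asks how the acetylation state of histones bears on epithelial-mesenchymal transition, the switch in which epithelial cells loosen their junctions and take on traits of mobile mesenchymal cells. The deposited normalised read counts covered 18679 genes, of which 18669 were tested. They summed to 48.4 to 52.7 M per library, and 43.4 to 59.9 M assigned reads per library were estimated from the spacing of the low values. MT-RNR2, a mitochondrial ribosomal RNA, was the highest gene in each library, and the mitochondrial ribosomal RNAs together held 18.3% to 23.5% of the normalised counts.

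Levels below are mean normalised read counts ± SD (n = 2), and changes are log2 differences of value + 1 ± SE from limma. On that scale the folds of weakly expressed genes are understated. The p-values measure only the spread between these libraries, since the labels do not say whether the 2 libraries of a group came from separate cultures. The main axis of variation, with 82.4% of the variance, placed the control libraries at -88.9 and -89.3, the 1 mM libraries at -16.9 and -25.4, and the 6 mM libraries at 102 and 118. Across 12661 genes, which are not independent of each other, the difference between the 2 libraries of a group followed the GC content of the transcripts, with rank correlations of 0.434 in the control, -0.479 at 1 mM and -0.474 at 6 mM.

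At 1 mM VPA, 1518 genes rose and 273 fell against the control, in answer to the question of what the lower dose changed. CDH1 (ENSG00000039068, chromosome 16, 68737225 to 68835548), which encodes the epithelial adhesion protein E-cadherin, rose from 740 ± 29 to 1381 ± 291. FN1, which encodes the matrix protein fibronectin and is often used as a mesenchymal marker, rose from 194 ± 9.90 to 332 ± 1.41. SNAI2 (ENSG00000019549, chromosome 8, 48917604 to 48921740), the gene of the transition factor SLUG, rose from 4.00 ± 1.41 to 25.0 ± 1.41. Of the measured neuronal, interferon-response and basement-membrane genes 14 of 24, 15 of 27 and 8 of 18 rose, and 3 of 36 genes of G1/S and replication fell. The camera calls of these 4 lists were lost with an estimated correlation, with adjusted p = 0.381, 0.381, 0.381 and 0.328.

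Among the called protein-coding genes with a mean of at least 100 in the higher group, the largest rise at 1 mM was that of CREB3L3 (ENSG00000060566, chromosome 19, 4153601 to 4173054), a transcription factor typical of liver and gut. It went from 23.5 ± 6.36 to 513 ± 106, a log2 change of 4.40 ± 0.24. DNAJC12, a co-chaperone, rose 19.7-fold and SLC16A7, which encodes the monocarboxylate transporter MCT2, rose 14.1-fold. KIF5C, a neuronal kinesin heavy chain, and NOVA2, a neuronal splicing regulator, rose 11.9-fold and 11.1-fold. IGF2, a fetal growth factor gene, rose 10.7-fold, but 73.7% of its exonic bases are shared with other genes on the same strand, so the assignment of its reads is uncertain. The largest fall within the same limits was that of NKX6-2 (ENSG00000148826, chromosome 10, 132783179 to 132786052), a homeobox gene of the nervous system, from 1363 ± 231 to 306 ± 12.7, a log2 change of -2.14 ± 0.24. PLPPR3, a membrane protein of neurons, fell to 0.457 of its control level.

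Among 27 measured epithelial genes 6 rose and 2 fell at 1 mM (10 and 3 adjusted over the list alone), with a median log2 change of 0.41 and limma camera adjusted p = 0.0390, or adjusted p = 0.610 with an estimated correlation. SPINT1, an epithelial protease inhibitor, rose 4.32-fold, and CLDN1, a tight-junction protein, rose 2.51-fold. EPCAM, an epithelial surface protein, had a log2 difference of 0.14 ± 0.21 and KRT19, a ductal keratin, of -0.30 ± 0.21, and neither was called. Of 26 measured mesenchymal genes 16 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 0.76 and adjusted p = 1.24e-09, or adjusted p = 0.216 with an estimated correlation. COL6A3, a collagen VI chain, rose 3.11-fold. VIM, the mesenchymal filament vimentin, was among the most abundant messages at 94972 ± 6208 in the control and had a log2 difference of 0.11 ± 0.19, which was not called. Its locus shares 24.4% of its exonic bases with antisense genes. CDH2, which encodes N-cadherin, had a log2 difference of 0.35 ± 0.14 without a call.

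The 14 measured transition factors had 3 risers and 0 fallers at 1 mM (4 and 0 adjusted over the list alone), with a median of 0.14 and camera adjusted p = 0.107. KLF8, a factor known to repress CDH1, rose 5.81-fold beside SNAI2. ZEB1 and SNAI1, both repressors of CDH1, had log2 differences of 0.20 ± 0.34 and -0.0029 ± 0.24 and were not called. Of 31 measured TGF-beta signalling genes 2 rose (2 adjusted over the list alone), among them INHBA, the activin A subunit, at 3.17-fold, and camera did not call the list (adjusted p = 0.820). TGFB1 had a log2 difference of -0.13 ± 0.23 without a call. Metalloproteinases and their inhibitors had 4 risers among 18 (6 adjusted over the list alone), with adjusted p = 2.43e-04, or adjusted p = 0.381 with an estimated correlation, and TIMP2, an inhibitor of these proteases, rose 2.99-fold. Laminin and basement-membrane genes had 8 risers among 18 (9 up and 1 down adjusted over the list alone), with a median of 0.81 and adjusted p = 5.36e-06, or adjusted p = 0.381 with an estimated correlation. COL4A5, a collagen IV chain of that list, rose 3.34-fold.

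Interferon-response genes had the lowest adjusted p of all lists at 1 mM, with 15 of 27 measured members risen and 0 fallen (25 and 0 adjusted over the list alone), a median log2 change of 1.15 and adjusted p = 7.03e-14, or adjusted p = 0.381 with an estimated correlation. OAS1, an antiviral oligoadenylate synthetase, rose from 37.0 ± 8.49 to 368 ± 106. MX1 (ENSG00000157601, chromosome 21, 41420304 to 41459214), an antiviral GTPase, rose from 535 ± 19.1 to 3010 ± 645. Inflammation and NF-kB genes had 10 risers among 22 (11 adjusted over the list alone), with adjusted p = 9.75e-06, or adjusted p = 0.381 with an estimated correlation, and PTGS2, the inducible cyclooxygenase, rose 4.44-fold. Antigen presentation genes and ligands of natural killer cells had 6 risers among 26 (8 adjusted over the list alone), with adjusted p = 0.00261, or adjusted p = 0.418 with an estimated correlation. Neuronal genes had 14 risers among 24 (16 adjusted over the list alone), with a median of 1.24 and adjusted p = 6.58e-08, or adjusted p = 0.381 with an estimated correlation. SCG2, the granule protein secretogranin II, rose 11.8-fold, and NCAM1, a neural adhesion protein, rose 5.79-fold.

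Among 36 measured genes of G1/S and DNA replication 0 rose and 3 fell at 1 mM (0 and 7 adjusted over the list alone), with a median of -0.36 and adjusted p = 8.42e-07, or adjusted p = 0.328 with an estimated correlation. TK1, thymidine kinase, and MCM7, a subunit of the replicative helicase, fell by log2 0.59 and 0.52. Genes of G2/M and mitosis had 2 fallers among 30 (0 adjusted over the list alone), with a median of -0.29 and adjusted p = 4.45e-04, or adjusted p = 0.503 with an estimated correlation. Replication-dependent histone genes, near-identical copies between which reads are uncertainly divided, had 1 faller among 24 (1 adjusted over the list alone), with adjusted p = 1.76e-04, or adjusted p = 0.407 with an estimated correlation. MKI67, the proliferation marker Ki-67, had a log2 difference of 0.15 ± 0.40 and was not called. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), which encodes the cell-cycle inhibitor p21, rose from 930 ± 25.5 to 2203 ± 325, and CCND2, a D-type cyclin, rose 6.25-fold. MYC had a log2 difference of -0.30 ± 0.16 without a call. The list of MYC and ribosome biogenesis genes had 1 faller among 25 (1 adjusted over the list alone), a median of -0.35 and adjusted p = 1.76e-04, or adjusted p = 0.381 with an estimated correlation.

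Smaller shifts at 1 mM were called for 3 further lists. Fatty acid oxidation genes had 3 risers among 23 (4 adjusted over the list alone; adjusted p = 0.0202, or adjusted p = 0.381 with an estimated correlation), with PLIN2, a lipid droplet protein, up 2.77-fold. RAS-MAPK feedback genes had 3 risers among 23 (3 adjusted over the list alone; adjusted p = 0.0484, or adjusted p = 0.610 with an estimated correlation). Heat-shock genes had 1 faller among 13 (1 adjusted over the list alone; adjusted p = 0.0452, or adjusted p = 0.381 with an estimated correlation). The class I deacetylase genes HDAC1, HDAC2, HDAC3 and HDAC8 had log2 differences of -0.03 ± 0.15, -0.05 ± 0.17, 0.03 ± 0.14 and 0.32 ± 0.24, none of them called. H1F0, a linker histone gene known to respond to deacetylase inhibitors, had a difference of 0.14 ± 0.16 without a call. Among 14 genes listed as known to rise under such inhibitors 4 rose and 0 fell (4 and 0 adjusted over the list alone). Their median was -0.11 and their mean 0.19, and camera did not call the list (adjusted p = 0.899).

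The test at 1 mM was limma's moderated test over all 6 libraries, and 15 of 41 lists were called by camera (10 up and 5 down), 0 with an estimated correlation, where the lowest adjusted p = 0.216, and 10 by fry. The count of 1791 changed genes became 640 and 738 without control library 1 or 2, 278 and 560 without 1 mM library 1 or 2, and 3879 and 3902 without 6 mM library 1 or 2. The 273 falls became 16, 16, 7 and 8 without a control or 1 mM library, 1464 and 1480 without a 6 mM library and 176 under upper-quartile scaling, and 30 of the 98 called genes that the naming rule chose stayed called in all 6 of these fits. CDH1 was not called without control library 1 (adjusted p = 0.0995), control library 2 (0.127), 1 mM library 1 (0.156) or the variance trend (0.0539), within a range of 0.00256 to 0.156 over all alternatives. FN1 was not called without any single control or 1 mM library (0.142 to 0.205) or without the variance trend (0.0781), within 0.00264 to 0.205. TK1 and MCM7 likewise were not called without these libraries (0.170 to 0.210 and 0.197 to 0.248), without the trend (0.0608 and 0.0814) or with the replicate block (0.0592 and 0.0841), within 0.00440 to 0.210 and 0.00477 to 0.248, and SNAI2 not without 1 mM library 1 (0.0536, within 0.00126 to 0.0536). Without 1 mM library 1 the adjusted p values of the epithelial, G2/M, fatty acid oxidation, heat-shock, antigen presentation and RAS-MAPK lists were 0.156, 0.116, 0.1004, 0.139, 0.0506 and 0.113. Without control library 1 they were 0.135, 0.135, 0.0668, 0.125 and 0.180 for the same lists other than antigen presentation, and without 6 mM library 1 or 2 that of the epithelial list was 0.0560 or 0.0553. With a mean of at least 50 as filter the calls of the epithelial, fatty acid oxidation, heat-shock and RAS-MAPK lists ended (0.0618, 0.0583, 0.0684 and 0.0618), with the replicate block that of the RAS-MAPK list (0.0563), and with only the 2 groups that of the epithelial list (0.0554). By fry the epithelial, histone, G2/M, heat-shock, antigen presentation, NF-kB, RAS-MAPK and MYC lists were not called (0.0678, 0.117, 0.339, 0.0951, 0.0548, 0.0548, 0.101 and 0.0714). For each list called in any comparison, the highest adjusted p over all alternatives was that with an estimated correlation.

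**Figure D1:**
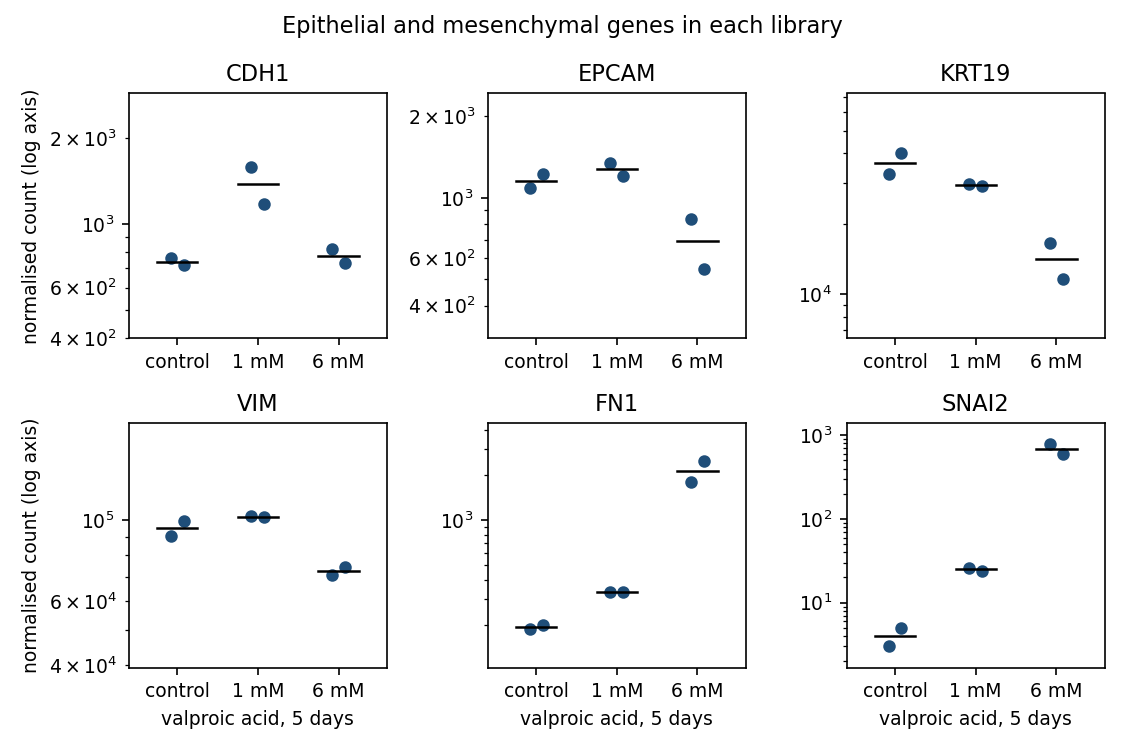
Normalised read counts (log axis) of CDH1, EPCAM, KRT19, VIM, FN1 and SNAI2, with 1 point per library and a bar at the group mean, for control, 1 mM and 6 mM VPA. CDH1 stood at 740, 1381 and 774 on average, SNAI2 at 4.00, 25.0 and 689, and FN1 at 194, 332 and 2127.

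At 6 mM VPA, 5227 genes rose and 4539 fell against the control, though 4882 rose and 4956 fell under TMM scaling and 4977 and 4797 under upper-quartile scaling. This comparison asks what the higher dose changed. SNAI2 rose 172-fold to 689 ± 122 and FN1 rose 10.96-fold to 2127 ± 472, whereas CDH1 stood at 774 ± 59.4, a log2 difference of 0.06 ± 0.17 that was not called. The epithelial genes EPCAM and KRT19 fell to 0.5997 and 0.388 of their control levels. Of the genes of G1/S and replication, G2/M and replication-dependent histones 31 of 36, 28 of 30 and 23 of 24 fell, with camera calls that were lost with an estimated correlation (adjusted p = 0.288, 0.293 and 0.293). MKI67 went from 20714 ± 5433 to 4517 ± 1829. CDKN1A rose 8.97-fold to 8344 ± 21.9.

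ANKRD1 (ENSG00000148677, chromosome 10, 90912096 to 90921276), a known target of the co-activator YAP, had the largest fitted rise at 6 mM, from 3.00 ± 1.41 to 2717 ± 890. STMN2 (ENSG00000104435, chromosome 8, 79610814 to 79666175), a microtubule regulator of growing neurons, was at 0 in both control libraries and reached 585 ± 256, at least 388-fold higher against a floor of 3 reads over the control group. ABCB1, the multidrug efflux pump P-glycoprotein, rose to 687 ± 122 from an estimated 1 control read, a ratio of 1373 with a 95% counting interval of 250 to 55048. KRT20, a keratin of gut epithelium, rose to 1067 ± 431 at a ratio of 1066 (interval 288 to 8597), and DCLK1, a kinase of neurons and tuft cells, to 496 ± 17 at a ratio of 992 (interval 178 to 39394). These intervals and floors cover counting error only. NKX6-2 fell from 1363 ± 231 to 21.0 ± 7.07, a log2 change of -5.98 ± 0.24. FBXO43, an inhibitor of the anaphase-promoting complex, fell to 0.0877 and PIF1, a DNA helicase, to 0.0917 of the control level. CCL5, a chemokine, fell to 0.0963 of it.

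Of 27 measured epithelial genes 10 rose and 11 fell at 6 mM (10 and 11 adjusted over the list alone), with a median of 0.03 and no camera call (adjusted p = 0.946), though fry called it up (adjusted p = 0.0392). MAL2, an epithelial trafficking protein, went from 0 in both control libraries to 161 ± 51.6, at least 106-fold, and ESRP1, an epithelial splicing regulator, rose 10.6-fold. MUC1, a mucin of the cell surface, fell to 0.204 of its control level. Of 26 mesenchymal genes 20 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 1.43 and adjusted p = 2.61e-05, or adjusted p = 0.288 with an estimated correlation. VCAN, a matrix proteoglycan, reached 1060 ± 767 from 4.5 ± 3.54, and COL5A1, a collagen V chain, rose 7.62-fold. VIM and CDH2 had log2 differences of -0.39 ± 0.19 and 0.23 ± 0.14 without a call.

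Transition factors at 6 mM had 4 of 14 risen and 3 fallen (4 and 3 adjusted over the list alone), a median of -0.05, a mean of 0.76 and no camera call (adjusted p = 0.715, direction up), though fry called the list up (adjusted p = 0.00651). Of all 18669 tested genes 5227 rose and 4539 fell at this dose. The counts of transition factors, and those of the TGF-beta genes below, lay near that share. KLF8 rose 17.6-fold. ZEB1 and SNAI1 had log2 differences of 0.47 ± 0.34 and 0.48 ± 0.24 and were not called. TGF-beta signalling genes had 10 risers and 8 fallers among 31 (10 and 8 adjusted over the list alone) and no camera call (adjusted p = 0.667; fry up, adjusted p = 0.00335), with INHBA up 8.18-fold, the inhibitory SMAD6 down to 0.374 of control, and TGFB1 at -0.02 ± 0.23 without a call. Metalloproteinases and inhibitors had 13 risers among 18 (14 adjusted over the list alone), with adjusted p = 3.84e-05, or adjusted p = 0.293 with an estimated correlation. MMP1, an interstitial collagenase, rose 177-fold and TIMP2 21.8-fold. Laminin and basement-membrane genes had 14 risers and 1 faller among 18 (14 and 1 adjusted over the list alone), with adjusted p = 3.14e-05, or adjusted p = 0.293 with an estimated correlation, and LAMA1 rose 71.0-fold. Actin cytoskeleton and adhesion genes had 14 risers and 2 fallers among 28 (14 and 2 adjusted over the list alone), with adjusted p = 0.0283, or adjusted p = 0.589 with an estimated correlation, and RHOB, a small GTPase of actin control, rose 6.32-fold.

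Genes of G1/S and replication had 31 fallers and 1 riser among 36 at 6 mM (31 and 2 adjusted over the list alone), with a median of -1.36 and adjusted p = 1.81e-11, or adjusted p = 0.288 with an estimated correlation. CDC45, a partner of the replicative helicase, fell to 0.183 of the control. Genes of G2/M and mitosis had 28 fallers among 30 (28 adjusted over the list alone), with a median of -1.91 and adjusted p = 6.88e-12, or adjusted p = 0.293 with an estimated correlation, and KIF20A, CCNB2 and AURKB fell to 0.123, 0.147 and 0.164. Replication-dependent histone genes had 23 fallers and 1 riser among 24 (23 and 1 adjusted over the list alone), with a median of -2.30 and adjusted p = 1.81e-11, or adjusted p = 0.293 with an estimated correlation. CCND2 rose 99.2-fold, while CDKN2C, an inhibitor of the kinases that D-type cyclins drive, fell to 0.163. MYC had a log2 difference of 0.04 ± 0.16 without a call, and its list with ribosome biogenesis had 3 risers and 12 fallers among 25 (3 and 12 adjusted over the list alone), with adjusted p = 0.0451, or adjusted p = 0.560 with an estimated correlation.

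Called chromatin genes went in both directions at 6 mM, as did called genes in general. Histone acetyltransferase genes had 8 fallers and 1 riser among 12 (8 and 1 adjusted over the list alone), with adjusted p = 0.0146, or adjusted p = 0.293 with an estimated correlation, and KAT6B and CREBBP fell to 0.274 and 0.459 of the control. Polycomb and DNA methylation genes had 10 fallers and 5 risers among 22 (11 and 5 adjusted over the list alone), with adjusted p = 0.0476, or adjusted p = 0.293 with an estimated correlation, and DNMT1, the maintenance DNA methyltransferase, and EZH2, the polycomb methyltransferase, fell to 0.188 and 0.420. Deacetylase genes had 5 risers and 5 fallers among 18 (5 and 5 adjusted over the list alone), near the share of all tested genes, and no camera call (adjusted p = 0.963), with HDAC9 up 5.77-fold and HDAC6, a tubulin deacetylase, down to 0.327. HDAC1 rose 1.56-fold and HDAC3, whose call was lost under 9 of the alternatives, 1.34-fold, while HDAC2 and HDAC8 had log2 differences of 0.24 ± 0.17 and 0.33 ± 0.24 without a call. H1F0 fell to 0.657 of the control. The 14 genes listed as known to rise under deacetylase inhibitors had 4 risers and 6 fallers (5 and 6 adjusted over the list alone), a median of -0.14, a mean of 0.17 and no camera call (adjusted p = 0.714, direction down), and the fallers included HIST2H2BE at 0.246 of control.

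Neuronal genes had 21 risers among 24 at 6 mM (21 adjusted over the list alone), with a median of 2.604 and adjusted p = 5.79e-08, or adjusted p = 0.293 with an estimated correlation, and NCAM1 rose 76.4-fold. Pancreatic endocrine genes had 4 risers among 5 (4 adjusted over the list alone), with adjusted p = 0.0223, or adjusted p = 0.293 with an estimated correlation, and NEUROG3, the endocrine progenitor factor, went from 0 in both control libraries to 26.0 ± 1.41, at least 17.2-fold. Cancer-testis antigen genes had 5 risers and 1 faller among 7 (5 and 1 adjusted over the list alone), with adjusted p = 0.0476, or adjusted p = 0.299 with an estimated correlation, and MAGEA4 rose 36.7-fold, though reads of this family of similar genes are uncertainly divided. Only 5 of 21 listed endocrine, 7 of 20 cancer-testis and 25 of 35 neuronal genes were in the table. Genes silent in the control could enter these counts only by rising, so the calls lean upward. Stemness genes had 8 risers and 1 faller among 13 (9 and 1 adjusted over the list alone), with adjusted p = 0.0187, or adjusted p = 0.293 with an estimated correlation, and Notch genes 12 risers and 3 fallers among 21 (12 and 3 adjusted over the list alone), with adjusted p = 0.0269, or adjusted p = 0.483 with an estimated correlation. Markers of other cell types had too few measured members for a list test. Only 3 of 11 listed endothelial, 2 of 15 blood-cell and 3 of 21 acinar genes were in the table, so most of these markers were absent. KDR and ESAM of the endothelium reached 335 ± 14.1 and 149 ± 16.3, CSF1R and CD14 of blood cells 84.5 ± 6.36 and 77.5 ± 4.95, and 2 of 3 acinar genes rose, with PRSS3, a trypsinogen, at 1241 ± 277.

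Inflammation and NF-kB genes had 16 risers and 3 fallers among 22 at 6 mM (16 and 3 adjusted over the list alone), with adjusted p = 2.75e-04, or adjusted p = 0.448 with an estimated correlation. CXCL8, the chemokine interleukin 8, rose 23.6-fold to 26308 ± 1170, and PTGS2 rose 43.1-fold. Antigen presentation genes had 11 risers and 2 fallers among 26 (11 and 2 adjusted over the list alone), with adjusted p = 0.0230, or adjusted p = 0.487 with an estimated correlation, and CD274, the checkpoint ligand PD-L1, rose 8.02-fold. Interferon-response genes had 4 risers and 10 fallers among 27 (4 and 10 adjusted over the list alone), a median of -0.48 and no camera call (adjusted p = 0.118), and IFIT2 and IFIT3 fell to 0.152 and 0.144 of the control. Lysosome and autophagy genes had 21 risers among 25 (21 adjusted over the list alone), with adjusted p = 1.07e-05, or adjusted p = 0.293 with an estimated correlation, and GABARAPL1, an autophagosome protein, rose 3.89-fold. Antioxidant genes under NRF2 had 9 risers and 1 faller among 16 (11 and 1 adjusted over the list alone), with adjusted p = 0.0102, or adjusted p = 0.455 with an estimated correlation. Amino acid and ER stress genes had 14 risers and 1 faller among 22 (14 and 1 adjusted over the list alone), with adjusted p = 0.00540, or adjusted p = 0.443 with an estimated correlation, and SLC7A11, the cystine transporter, rose 4.56-fold. Fatty acid oxidation genes had 15 risers and 2 fallers among 23 (15 and 2 adjusted over the list alone), with adjusted p = 0.00396, or adjusted p = 0.293 with an estimated correlation, and PPARGC1A, a co-activator of mitochondrial genes, went from 0 in both control libraries to 109 ± 26.9, at least 72.2-fold.

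At 6 mM camera called 21 of 41 lists (15 up and 6 down), 0 held with an estimated correlation, where the lowest adjusted p = 0.288, and fry called 32. With an estimated correlation the G2/M list, with 28 of 30 members fallen, did not have the strongest camera result before adjustment. Those of the G1/S, mesenchymal, neuronal and histone lists were stronger. The power of that setting was not tested, so the lost calls do not show whether these lists changed. Without control library 2 the count of changed genes was 6399 in place of 9766, and 179 of the 218 called genes chosen by the naming rule stayed called without each of the 6 libraries. Without that library EPCAM (adjusted p = 0.0971), H1F0 (0.114), HDAC1 (0.0980) and HDAC3 (0.0910) were not called, nor was the polycomb list (0.0529). HDAC3 was not called without control library 1 (0.216), 1 mM library 1 (0.0535) or 1 mM library 2 (0.0537) either, nor under TMM (0.0535) or upper-quartile scaling (0.0504), without the variance trend (0.0682), with the replicate block (0.0641) or with only the 2 groups (0.0540). Over all alternatives the adjusted p ranged from 1.71e-04 to 0.0971 for EPCAM, 0.00232 to 0.114 for H1F0, 0.00196 to 0.0980 for HDAC1 and 0.00791 to 0.216 for HDAC3. Without 6 mM library 1 the calls of the acetyltransferase, polycomb, antigen presentation, actin and cancer-testis lists ended at adjusted p = 0.0658, 0.0993, 0.0744, 0.101 and 0.138. Those of the MYC and actin lists ended without control library 1 (both 0.0761), those of the MYC and cancer-testis lists without 6 mM library 2 (0.0519 and 0.0989), and that of the polycomb list without 1 mM library 1 or 2 (0.0537 and 0.0530). With a mean of at least 50 as filter the calls of the polycomb, Notch, MYC, actin and cancer-testis lists ended (0.0649, 0.0728, 0.0599, 0.0515 and 0.255), and after GC correction those of the polycomb and cancer-testis lists (0.0542 and 0.0686). The polycomb call also ended with only the 2 groups (0.0524) and the cancer-testis call with the numbers of the control libraries exchanged in the block (0.0766).

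**Figure D2:**
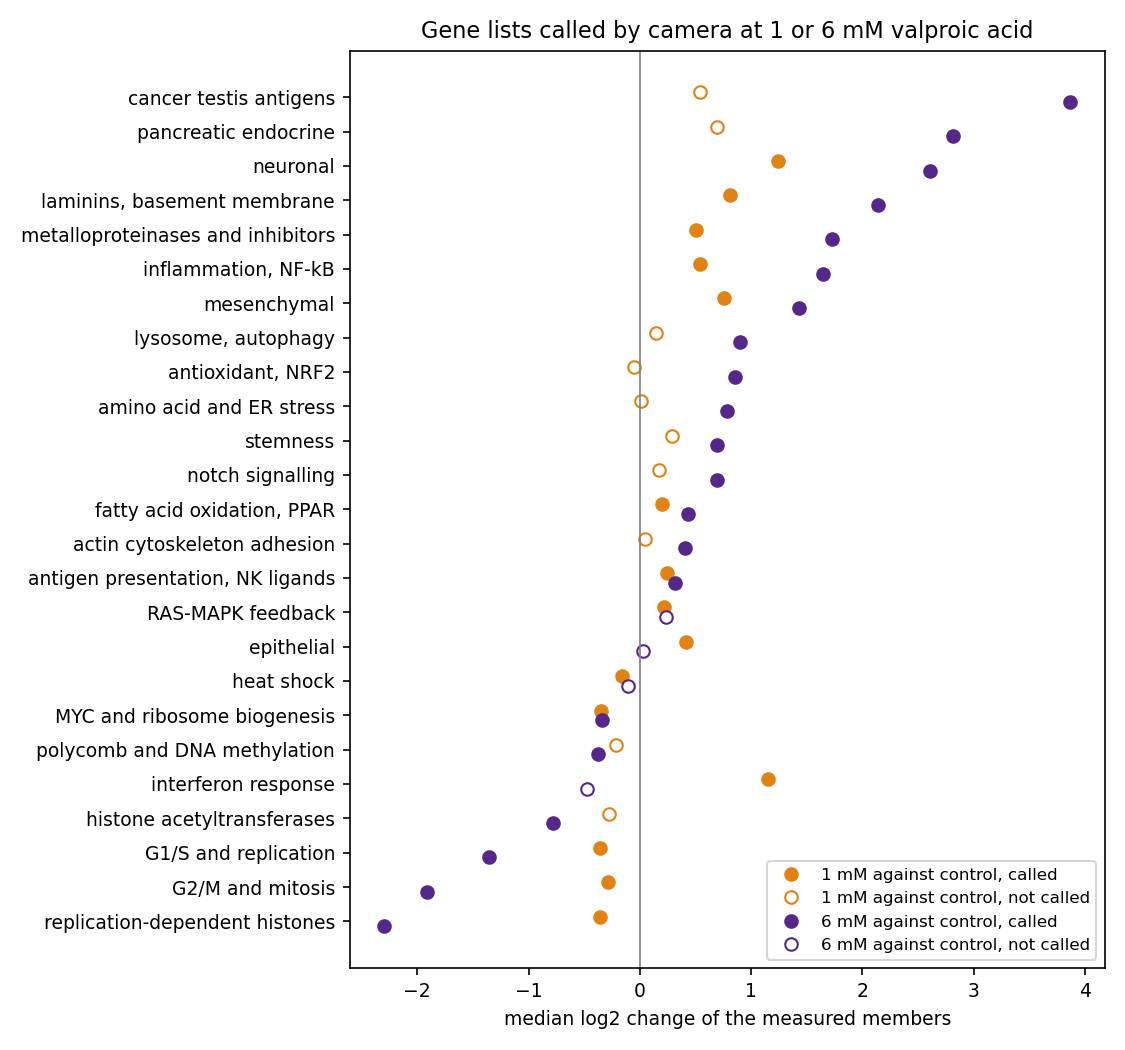
Median log2 change of each gene list called at 1 mM or 6 mM VPA against control, with filled points where called and open points where not. The neuronal list lay at 1.24 and 2.604, the interferon list at 1.15 and -0.48, and the G2/M list at -0.29 and -1.91.

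Between the doses, which asks what 6 mM VPA changed beyond 1 mM, 3623 genes were higher and 2729 lower at 6 mM, against 3304 and 3168 under TMM scaling and 3132 and 3325 under upper-quartile scaling. CDH1 was lower at 6 mM than at 1 mM, at 774 ± 59.4 against 1381 ± 291, a log2 change of -0.82 ± 0.17. EPCAM and KRT19 fell as well, to 0.543 and 0.480 of their 1 mM levels, while SNAI2 was 27.6-fold and FN1 6.41-fold higher. MX1 fell from 3010 ± 645 to 216 ± 53.7, and interferon-response genes in general stood below their 1 mM levels. The cell-cycle lists were lower and the neuronal, lysosome and metalloproteinase lists higher than at 1 mM. All these list calls, that of the interferon list included, were lost with an estimated correlation, with adjusted p = 0.238 for G1/S genes and 0.2997 for the others.

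ANKRD1 and KRT20 were 340-fold and 427-fold higher at 6 mM than at 1 mM. MYCT1 was at 0 in both 1 mM libraries and at 106 ± 5.66 at 6 mM, at least 72.0-fold higher. PDE7B, a cyclic AMP phosphodiesterase, was 126-fold and ITIH5, a hyaluronan-binding matrix protein, 123-fold higher. MUC5AC, a gel-forming mucin, fell from 138 ± 3.54 to 14.5 ± 7.78, and ITGA10, a collagen-binding integrin, fell to 0.103 of its 1 mM level. IFITM1, an antiviral membrane protein, fell to 0.0294, but 32.5% of its exonic bases are shared with IFITM2, so its reads are uncertainly assigned.

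Interferon-response genes had 21 fallers and 0 risers among 27 between the doses (22 and 0 adjusted over the list alone), with a median log2 change of -1.45 and adjusted p = 1.77e-11, or adjusted p = 0.2997 with an estimated correlation. OAS2, an antiviral synthetase, fell from 207 ± 42.4 to 13.0 ± 2.83, and IFIT3 fell to 0.0915 of its 1 mM level. Inflammation and NF-kB genes had 13 risers and 2 fallers among 22 (14 and 2 adjusted over the list alone), with adjusted p = 0.00224, or adjusted p = 0.508 with an estimated correlation, and CXCL8 rose 9.59-fold.

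**Figure D3:**
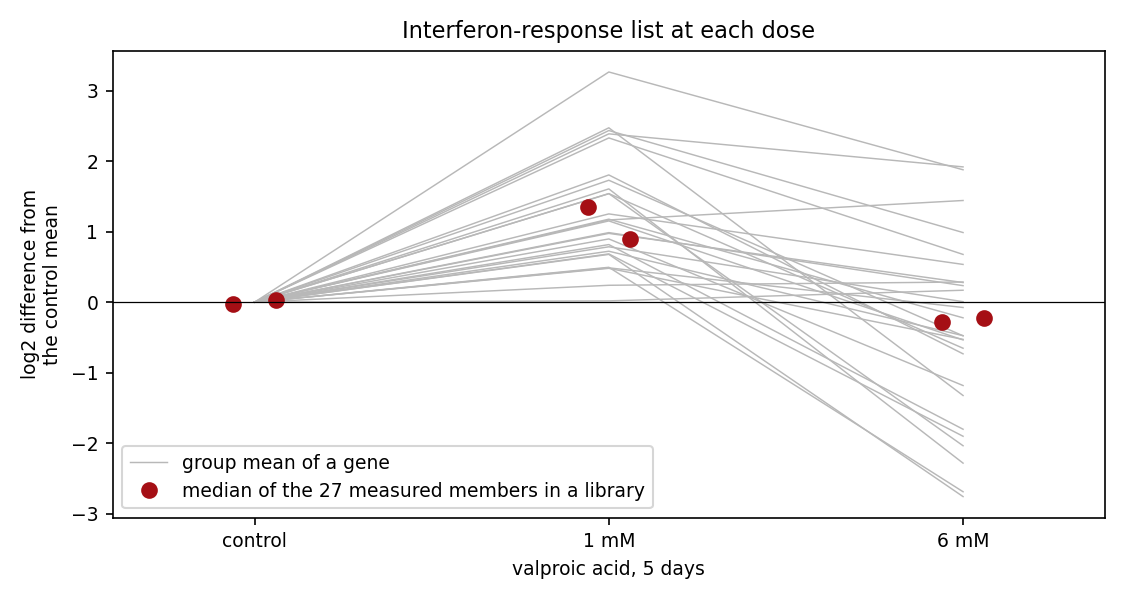
Log2 difference from the control mean of the 27 measured interferon-response genes (grey lines through the group means) and the list median of each library (points) for control, 1 mM and 6 mM VPA. The medians were 1.36 and 0.89 in the 1 mM libraries and -0.29 and -0.23 in the 6 mM libraries.

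Of 26 mesenchymal genes 12 rose and 4 fell between the doses (13 and 5 adjusted over the list alone), with adjusted p = 0.0164, or adjusted p = 0.2997 with an estimated correlation. COL5A1 rose 4.53-fold, whereas COL6A3 and COL5A2, also collagen chains, fell to 0.453 and 0.495. Epithelial genes had 7 risers and 9 fallers among 27 (8 and 11 adjusted over the list alone), a median of -0.36, a mean of 0.15 and no camera call (adjusted p = 0.359, direction down). Transition factors had 3 risers and 3 fallers among 14 (3 and 3 adjusted over the list alone), a median of -0.29, a mean of 0.26 and no camera call (adjusted p = 0.914, direction down). TGF-beta signalling genes had 9 risers and 5 fallers among 31 (10 and 6 adjusted over the list alone) and no camera call (adjusted p = 0.527; fry up, adjusted p = 0.0119), with TGFBR2, the type II receptor, up 2.37-fold. Metalloproteinases and inhibitors had 9 risers among 18 (9 adjusted over the list alone), with adjusted p = 2.08e-04, or adjusted p = 0.2997 with an estimated correlation, and MMP1 rose 32.8-fold. Laminin and basement-membrane genes had 11 risers and 1 faller among 18 (13 and 1 adjusted over the list alone), with adjusted p = 2.96e-04, or adjusted p = 0.310 with an estimated correlation. VIM, CDH2, ZEB1, SNAI1 and TGFB1 had log2 differences of -0.49 ± 0.19, -0.11 ± 0.14, 0.27 ± 0.34, 0.48 ± 0.24 and 0.11 ± 0.23, none of them called.

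The cell-cycle lists fell between the doses, with 27 of 36 G1/S and replication genes, 27 of 30 G2/M genes and 21 of 24 histone genes fallen and 0, 0 and 1 risen (31, 29 and 22 fallen and 1, 0 and 1 risen adjusted over the list alone). Their camera adjusted p values were 1.90e-13, 1.07e-15 and 3.76e-14, with adjusted p = 0.238, 0.2997 and 0.2997 with an estimated correlation. DNMT1 fell to 0.283 and MKI67 to 0.186 of the 1 mM level. CDKN1A rose 3.79-fold and CCND2 15.9-fold. Histone acetyltransferase genes had 6 fallers and 1 riser among 12 (8 and 1 adjusted over the list alone) and polycomb and DNA methylation genes 8 fallers and 3 risers among 22 (8 and 3 adjusted over the list alone), with adjusted p = 0.0164 and 0.0477, or adjusted p = 0.2997 for each with an estimated correlation. HDAC9 rose 3.37-fold and HDAC1 1.60-fold, while HDAC2, HDAC3 and HDAC8 had log2 differences of 0.29 ± 0.17, 0.40 ± 0.14 and 0.01 ± 0.24 without a call. H1F0 fell to 0.591, and MYC had a log2 difference of 0.33 ± 0.16 without a call.

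Neuronal genes had 19 risers among 24 between the doses (19 adjusted over the list alone), with adjusted p = 7.62e-08, or adjusted p = 0.2997 with an estimated correlation, and UCHL1, a neuronal ubiquitin hydrolase, rose 8.67-fold. Lysosome and autophagy genes had 19 risers among 25 (20 adjusted over the list alone), with adjusted p = 1.54e-07, or adjusted p = 0.2997 with an estimated correlation, and MAP1LC3B, the autophagosome protein LC3B, rose 2.45-fold. Amino acid and ER stress genes had 13 risers and 1 faller among 22 (15 and 1 adjusted over the list alone), with adjusted p = 9.66e-05, or adjusted p = 0.2997 with an estimated correlation, and antioxidant genes 10 risers and 1 faller among 16 (12 and 1 adjusted over the list alone), with adjusted p = 2.96e-04, or adjusted p = 0.310 with an estimated correlation. HMOX1, heme oxygenase, rose 3.45-fold. Fatty acid oxidation genes had 10 risers among 23 (10 adjusted over the list alone), with adjusted p = 0.0164, or adjusted p = 0.310 with an estimated correlation. Genes encoded by mitochondrial DNA had 6 risers among 13 (6 adjusted over the list alone), with adjusted p = 0.0292, or adjusted p = 0.602 with an estimated correlation. Their messages held 3.43% and 3.49% of the counts in the control libraries, 4.20% and 3.24% at 1 mM and 5.00% and 4.79% at 6 mM.

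The lists of endocrine, Notch, stemness, actin and cancer-testis genes were higher between the doses with 3 of 5, 10 of 21, 6 of 13, 8 of 28 and 5 of 7 members risen and 0, 3, 1, 0 and 0 fallen (4, 10, 6, 7 and 5 risen and 0, 3, 1, 0 and 0 fallen adjusted over the list alone). Their adjusted p values were 0.0332, 0.0292, 0.0365, 0.02002 and 0.0186, and the same lists had adjusted p = 0.307, 0.508, 0.2997, 0.596 and 0.2997 with an estimated correlation. Most listed endocrine and cancer-testis genes were absent from the table, which favors rises among those measured. In none of the 3 comparisons did camera call 15 lists, whose adjusted p values lay between 0.0626 and 0.9749, but fry called 8 of them in at least 1 comparison, all up, with adjusted p between 0.00163 and 0.0316. The 15 were transition factors, TGF-beta signalling, deacetylases, genes known to rise under deacetylase inhibitors, cyclin-dependent kinase inhibitors with D-type cyclins, apoptosis, p53 targets, ductal genes, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, metallothioneins, Wnt signalling, ABC transporters and cytosolic ribosomal proteins. The median and mean of lists without a camera call also differed in sign at 1 mM for deacetylases (-0.03 and 3.1e-05), genes known to rise under deacetylase inhibitors (-0.11 and 0.19), p53 targets (-0.02 and 0.13), glycolysis (-0.03 and 0.02), antioxidant genes (-0.06 and 0.07) and metallothioneins (-0.07 and 0.05). At 6 mM they did so for cholesterol synthesis (-0.02 and 0.05), and between the doses for the inhibitor list (0.02 and -0.02) and metallothioneins (0.16 and -0.0067). The camera direction alone differed for ER stress at 1 mM (0.01 and 0.04, down), fatty acid synthesis at 6 mM (0.11 and 0.04, down) and Wnt genes between the doses (0.31 and 0.05, down).

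Between the doses camera called 21 of 41 lists (15 up and 6 down), 0 held with an estimated correlation, where the lowest adjusted p = 0.238, and fry called 25. The 6352 changed genes became 3185 without 1 mM library 1 and 2304 without 1 mM library 2, and 123 of the 193 called genes chosen by the naming rule stayed called without each of the 6 libraries. CDH1 and H1F0 were not called without 1 mM library 1 (adjusted p = 0.0700 and 0.0844, over all alternatives 0.00307 to 0.0700 and 0.00188 to 0.0844). EPCAM, KRT19 and HDAC1 were not called without 1 mM library 1 (0.0960, 0.0571 and 0.0944) or 1 mM library 2 (0.0717, 0.0610 and 0.0652), with ranges of 1.91e-04 to 0.0960, 1.74e-04 to 0.0610 and 0.00304 to 0.0944. Without 6 mM library 1 the calls of the acetyltransferase, polycomb, Notch, stemness, actin and cancer-testis lists ended at adjusted p = 0.0967, 0.108, 0.0765, 0.1002, 0.113 and 0.1002. Without 1 mM library 2 those of the polycomb, endocrine, Notch and mitochondrial lists ended (0.0502, 0.0535, 0.0627 and 0.141), without 1 mM library 1 those of the polycomb and stemness lists (0.0717 and 0.0762), and without 6 mM library 2 that of the stemness list (0.119). With a mean of at least 50 as filter the calls of the polycomb, fatty acid oxidation, Notch, stemness and cancer-testis lists ended (0.0546, 0.0546, 0.103, 0.0645 and 0.180). That of the polycomb list also ended with the replicate block (0.0510), that of the mitochondrial list by fry (0.0519), and both after GC correction (0.0538).

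The overlap of the doses asks how far the genes changed at 1 mM were also changed at 6 mM, and 1709 genes were called in the same direction at both, 1447 up and 262 down. CREB3L3, SCG2, KIF5C and NCAM1 were among those up at both, and NKX6-2 and PLPPR3 among those down at both. Independent lists of the same sizes would share 425 rises and 66.4 falls, and 95.3% of the rises and 96.0% of the falls at 1 mM were also called at 6 mM. Another 9 genes were called in opposite directions. Of the genes risen at 1 mM, 1032 were higher still at 6 mM, such as CCND2 and SNAI2, and 58 were lower at 6 mM than at 1 mM, such as COL6A3 and MX1. Of the 15 interferon-response genes that rose at 1 mM, 13 were among these 58 (two-sided Fisher's exact test among the 1518 risers, p = 9.04e-18, genes not being independent).

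Across all tested genes the log2 changes at the doses had a Pearson correlation of 0.80 and a covariance of 0.730, and 78.5% had the same sign. In 100 simulations of 3 unchanged groups, with the treated groups compared with the same controls, the averages were 0.50, 0.0399 and 66.7%, and 0.01 genes were called at both doses. As no gene changed in them, so few shared calls follow from the setting. That count does not measure how far the shared controls add to the observed overlap. The 2 control libraries cannot be divided between the comparisons with more than 1 library on each side, so part of the excess of shared calls over independent lists may come from the shared controls. The overlap was 621 and 721 without control library 1 or 2, 275 and 546 without 1 mM library 1 or 2, and 3527 and 3380 without 6 mM library 1 or 2. The 262 shared falls became 16, 15, 7, 8, 1328 and 1241 in the same order.

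**Figure D4:**
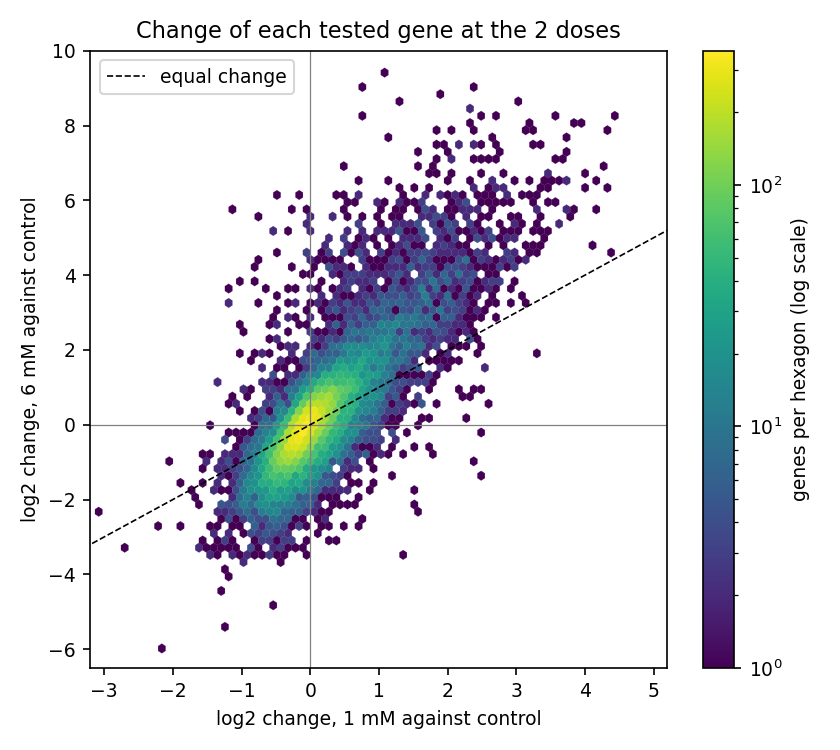
Log2 change at 6 mM against that at 1 mM VPA, each against control, with the color of each hexagon giving its number of tested genes and a dashed line at equal change. The Pearson correlation was 0.80, and 78.5% of the genes had the same sign on both axes.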

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

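Of the tests in this part, the comparison of the interferon list with matched random lists was chosen before its result was seen, and the tests of scaling and of a single 1 mM library after it. Each log2 change given for a gene here is that of 6 mM against 1 mM VPA. It comes from a direct limma test of the difference between the effects of the 2 doses against the same controls. For the list, medians over its members are given, at 1 mM or between the doses. The genes and the list were called at 1 mM and turned back at 6 mM. Both comparisons use the same 2 libraries at 1 mM, whose noise pushes the 2 changes in opposite directions.

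The interferon-response list was higher at 1 mM than in the control and lower at 6 mM than at 1 mM, with a median of -1.45 between the doses, though both calls were lost with an estimated correlation (adjusted p = 0.381 and 0.2997). Scaling of the libraries, which moves all genes alike, is argued against, since the median at 1 mM lay 1.15 above that of all genes, and so is a single library, since with either 1 mM library left out it was at least 0.89. Random lists matched on GC content, transcript length and level reached at most 0.38 at 1 mM in 10000 draws, and 0 of them were as low between the doses. Their genes were drawn separately, so these lists lack the correlation between interferon genes and their medians scatter less. The draws thus bear only on GC content, length and level. A dose-dependent interferon response, present at 1 mM and absent from the list median at 6 mM, may account for the pattern, as a hypothesis found and examined on the same data. Some members, such as OAS1, still stood above the control at 6 mM, while more members, such as IFIT3, fell below it. Culture conditions that differed between the groups stay open, since the labels give no batches.

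MX1, OAS1 and IFI27 of that list changed by -3.80, -1.39 and -1.45 between the doses. TNFSF10, which encodes the death ligand TRAIL, changed by -1.58. COL6A3, SPARC and PRRX1, all of the mesenchymal program, changed by -1.14, -0.90 and -0.90. CDH1 changed by -0.82. MEGF6 and ATAD3C, which fell at 1 mM, changed by 0.59 and 0.86, and ATAD3C has close paralogs between which reads are uncertainly divided. Only MX1 and COL6A3 kept both calls, at 1 mM and between the doses, without each of the 6 libraries.

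Left-out libraries ended the other calls as follows, with adjusted p in brackets. Between the doses they ended without 1 mM library 1 for OAS1 (0.0580), IFI27 (0.133), SPARC (0.123) and CDH1 (0.0700), without 1 mM library 2 for PRRX1 (0.0973), and without either for TNFSF10 (0.0618 and 0.0764). The call of MEGF6 between the doses stood only without 6 mM library 1 (0.0258, otherwise 0.0725 to 0.131), and that of ATAD3C only without 6 mM library 2 (0.00849, otherwise 0.0559 to 0.149). At 1 mM the calls ended without any single control or 1 mM library for ATAD3C (0.104 to 0.164) and PRRX1 (0.108 to 0.200), and without control library 1, control library 2 or 1 mM library 1 for CDH1 (0.0995, 0.127 and 0.156). They ended there without 1 mM library 1 for MEGF6 (0.0507), SPARC (0.0650) and IFI27 (0.0922), and without either 1 mM library for TNFSF10 (0.0869 and 0.0712).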

How the results depend on the processing

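Of the alternatives in this part, the GC correction per library and the exchanged numbers of the control libraries were chosen after seeing the data. The 543 results for named genes kept their direction and side of the threshold in 8454 comparisons with an alternative, lost a call in 584, gained a call in 28 and changed sign in 31, and the 57 called lists kept their call in 950 and lost it in 127. At a fold of at least 2, 1131, 5529 and 3189 genes were called at 1 mM, at 6 mM and between the doses, and 1066 were shared by the doses, because a condition was added. With only the 2 compared groups in the fit 3299, 8567 and 4805 genes were called and 2883 were shared, and the fit at 1 mM then left out the 6 mM libraries, whose squared difference between libraries was 10.6 times the Poisson variance in the median over genes (mean 142), against 2.96 in the control (mean 73.6) and 3.87 at 1 mM (mean 41.4). The 273 falls at 1 mM became 49 at a fold of at least 2, 176 under upper-quartile scaling, 132 without the variance trend, 166 with the replicate block, 672 with the exchanged numbers, 479 after GC correction, 1198 with only the 2 groups and 7 to 1480 without 1 library. Falls were 2544 to 5376 at 6 mM and 781 to 4107 between the doses without 1 library, and rises 271 to 2422, 3855 to 5687 and 1523 to 4305. Rises and falls were 4882 and 4956 at 6 mM under TMM scaling, and 3132 and 3325 between the doses under upper-quartile scaling, where falls outnumbered rises. With an estimated correlation 0, 0 and 0 lists were called, and fry called 32 at 6 mM. Leaving out 1 library gave 278 to 3902, 6399 to 11063 and 2304 to 8412 changed genes, 10 to 20, 16 to 20 and 14 to 21 called lists and 275 to 3527 shared genes, and the group left with 1 library is then assumed to vary like the others. Sign changes arose for genes without a call. At 1 mM SNAI1 had 0.0355 under upper-quartile scaling and 0.0738 after GC correction, and HDAC1 0.00638 under upper-quartile scaling. At 6 mM MYC had -0.0178 and -0.00623 under TMM and upper-quartile scaling, and TGFB1 0.0871 after GC correction. Between the doses HDAC8 had -0.0439 and -0.0726 under TMM and upper-quartile scaling. Leaving out 1 library moved log2 changes over these ranges. At 1 mM ZEB1 from -0.13 to 0.52, SNAI1 from -0.33 to 0.32, H1F0 from -0.0137 to 0.30, MKI67 from -0.40 to 0.71, HDAC1 from -0.19 to 0.12, HDAC2 from -0.14 to 0.037 and HDAC3 from -0.0805 to 0.14. At 6 mM CDH1 from -0.0141 to 0.14, ZEB1 from -0.0269 to 0.97, MYC from -0.15 to 0.22 and TGFB1 from -0.38 to 0.34. Between the doses ZEB1 from -0.22 to 0.77, HDAC8 from -0.25 to 0.26 and TGFB1 from -0.25 to 0.47. The cause of these differences was not tested. DESeq2 was not run, since whole reads were not recovered from the rounded values. No scaling moved the median log2 change of all genes by more than 0.1.

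With the replicate number as a block, 1594, 9287 and 5805 genes were called and 1514 shared, although the labels do not say whether the numbers pair the libraries. Deviations of libraries with the same number correlated at -0.19 between control and 1 mM and -0.213 between control and 6 mM. Between 1 mM and 6 mM the correlation was 0.17, so a pairing stays open. With the numbers of the control libraries exchanged the counts were 2648, 11030 and 7988.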

Other observations

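Pathways outside the lists were examined with KEGG, by a one-sided hypergeometric test of the called genes against 4981 tested genes that any pathway holds, adjusted over 1698 tests, all chosen after the results were seen. The same holds for the tests in this part, except that of a shift between scalings, which was chosen before its result was seen. Spliceosome genes fell in 78 of 127 cases at 6 mM where 27.6 were expected (adjusted p = 1.05e-19). At 1 mM 15 of them fell where 2.27 were expected (adjusted p = 6.11e-07), a result that rests on 273 falls in all, against 7 to 16 without any single control or 1 mM library. Genes of the Fanconi anemia pathway, which repairs cross-linked DNA, fell in 30 of 50 cases at 6 mM (10.9 expected, adjusted p = 6.11e-07), and those of base excision repair in 22 of 33 (7.16 expected, adjusted p = 3.36e-06). Cell adhesion molecules rose in 32 of 84 cases at 1 mM (9.29 expected, adjusted p = 1.38e-08) and 54 of 84 at 6 mM (30.5 expected, adjusted p = 1.10e-05). Phagosome genes rose in 67 of 109 cases at 6 mM (39.5 expected, adjusted p = 5.20e-06), and those of the synaptic vesicle cycle in 33 of 51 (18.5 expected, adjusted p = 0.00135). Genes of a pathway are not independent, so these p-values are too small by an unknown amount.

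More genes rose than fell at 1 mM, 84.8% of 1791 calls. All log2 changes would have to shift by 0.18 for rises no longer to outnumber falls, whereas the scalings tried differed by at most 0.04. Among genes with a mean of at least 1000 rises made up 72.3% of 451 calls (exact 95% interval 67.9 to 76.4), which argues against weakly expressed genes as the whole source. With the 6 mM libraries left out of the fit rises were 63.7% of 3299 calls (62.0 to 65.3), so their spread is not the whole source either, though the share was lower. Both intervals treat genes as independent and leave out differences between libraries, so they are too narrow by an unknown amount. The share of rises went from 93.7% of calls at a mean below 50 to 70.7% at a mean of at least 5000. The median log2 change of all genes at 1 mM was 0 on the median-scaled values. Neither these values nor the other scalings tried, which also equalise the libraries, can show a net gain of transcripts at 1 mM. Such a gain stays a hypothesis, and an absolute change in RNA per cell was not measured.

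Deviations of libraries with the same number correlated weakly between groups, at -0.19 (control and 1 mM), -0.213 (control and 6 mM) and 0.17 (1 mM and 6 mM). The 2 libraries of each group thus differed only in small part along an axis shared by the 3 groups. GC content of the transcripts fits as a trait of it that leaves much of the variation open, since the rank correlation with it across 12661 genes was at least 0.434 in size in each group. Transcript length beyond GC content is argued against only as a trait of that strength, since its correlation after removal of GC content, taken in the direction of the axis, was 0.0562 in the control, 0.158 at 1 mM and 0.111 at 6 mM, and a small part along the axis stays open. After a GC correction per library 2342, 10377 and 7374 genes were called at 1 mM, at 6 mM and between the doses. Differences in library preparation may underlie the axis, which no label records.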
